A study of Mus musculus with 6 samples.

How the data were processed

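RNA was sequenced in 6 libraries of RAW264.7, a mouse macrophage cell line, all induced with lipopolysaccharide (LPS). The series' design text puts 3 libraries in an untreated control group and 3 in a group treated with TPPU, a small-molecule inhibitor of soluble epoxide hydrolase. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was captured on oligo(dT) beads and fragmented, and the second cDNA strand was marked with dUTP, which keeps the strand. The labels give all libraries the same batch. They do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

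The authors deposited 1 table of FPKM (fragments per kilobase of gene, scaled to each library's total of fragments) for 18019 gene symbols in the 6 libraries. The unit is taken from the table's name and its values. The genome build is mm10 per the submitters' processing notes. The aligner, the counting program, the annotation and any filter are not given in the sources used here. Columns were matched to samples by the library name in each sample's description. For the TPPU samples the same description also cites a column of another table under a name that refers to an sh-LIS1 knockdown. That table was not used here, and the expression of Pafah1b1, the gene that encodes LIS1, was checked in every library.

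FPKM keeps no total count, so depth was estimated from the values. In genes with a single annotated transcript, low FPKM values are whole multiples of the value of 1 fragment, and the step gives the number of fragments. The estimates were 17.7, 22.5 and 19.1 M (mega) fragments in control replicates 1, 2 and 3, and 18.2, 22.8 and 21.2 M in TPPU replicates 1, 2 and 3. Between 91.0% and 92.1% of the low values used came out whole within 0.1 of a fragment, against 20.0% by chance. At these depths 1 fragment in a transcript of 1 kb is worth 0.0439 to 0.0565 FPKM. A floor of 3 fragments in 1 kb corresponds to 0.132 to 0.169 FPKM and covers counting error alone. No count model was applied.

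Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, which kept 9728 and left out 8291. The values were transformed as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. TPPU was compared with control in limma 3.58.1 (R 4.3.3) with a mean-variance trend and group as the sole term. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Genes below the filter were compared by a two-sided exact permutation test, which cannot give a p below 0.1 for 3 libraries against 3.

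Before the data were examined, 36 gene lists were written from textbook membership, and the 31 with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01. Camera asks whether a list's genes shift relative to all other genes. Each list was also tested with camera at a correlation estimated from the data. That form of camera uses the few residual degrees of freedom of the 6 libraries in place of the number of genes. A call can therefore be lost with it without a higher correlation. Fry was run as well, and asks whether the list's genes move, on balance, one way. The genes named in the text followed a rule of 3 parts fixed at the same time. They were the 10 largest rises and the 10 largest falls past the threshold in fully separated groups, 24 genes chosen from the study's title, and up to 4 members of each list described with the smallest adjusted p in the direction described. No gene met the first part. The result of 1 gene that the rule names is not reported here. Genes named outside the rule, Alb and Urah among them, were chosen after their values were seen.

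The alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, limma without the trend, sample quality weights, robust empirical Bayes, an added log2 fold change of at least 1, the replicate number as a block, and each library left out in turn. Removal of a trend with GC content or with transcript length, by a loess curve per library with a span of 0.3, was added after the data were seen. So was the IL-17 list without the genes it shares with other lists. GC content, length and positions came from the GENCODE M21 annotation of the same build, and 97.9% of the tested genes had GC and length values. Positions are 1-based.

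The scripts were tested on simulated data with the spread of the real genes. With 200 of 9728 genes changed, limma recovered 36% of genes at a fold of 1.5, 94.8% at a fold of 2 and 99.6% at a fold of 4. The simulated noise was independent between genes and libraries, so these shares are an upper guide. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.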

Results

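Expression was measured by poly(A) RNA sequencing in RAW264.7 cells, a mouse macrophage line, after induction with LPS, a bacterial product that drives macrophages towards the inflammatory M1 state. A control group (n = 3) was compared with a group treated with TPPU (n = 3), which inhibits soluble epoxide hydrolase, the enzyme that breaks down epoxyeicosatrienoic acids (EETs). The series title places the comparison in the setting of M1 polarization and the EETs, IL-17 and NF-κB pathways in osteoarthritis of the jaw joint. Estimated depth ranged from 17.7 to 22.8 M (mega) fragments per library. Values are FPKM, given as mean ± SD over 3 libraries per group.

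After TPPU, immediate-early genes, the transcription factors and phosphatases that respond first to a stimulus, were lower as a group, and so was a list of IL-17 signalling genes. Both calls were made by camera with a preset correlation. They were lost with an estimated correlation, a test that also has fewer degrees of freedom (camera adjusted p = 0.253 and 0.181). They were lost with fry too (adjusted p = 0.0986 and 0.115). Of 22 immediate-early genes measured, 20 had a negative change, with a median log2 fold change of -0.54, or -0.27 without control replicate 3. Egr1 measured 22.9 ± 6.06 in control and 10.5 ± 2.58 with TPPU, and Dusp1, a phosphatase that switches off MAP kinases, 19 ± 3.04 and 9.45 ± 0.73. Genes of ribosomal proteins and of oxidative phosphorylation were higher as groups, with median changes of 0.12 and 0.13, or 0.04 and 0.07 with a trend on transcript length removed, and these camera calls were lost too (adjusted p = 0.379 with an estimated correlation for each). The list of M1 inflammatory genes did not pass the test, with a median of -0.01 over 22 genes, or -0.1 without control replicate 3.

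No single gene passed the threshold in either direction. Over 9728 genes tested with limma, 0 were higher and 0 were lower, and the smallest adjusted p was 0.116. At an unadjusted p under 0.05 there were 768 genes, 408 higher and 360 lower, where chance gives 486. All 3 TPPU libraries lay above all 3 controls for 728 genes and below them for 767, where chance gives 486 in each direction (10% of genes in both together). Weighting the libraries by quality gave 89 higher and 80 lower genes, with control replicate 3 weighted at 0.19 and control replicate 1 at 3.84. Leaving out TPPU replicate 1 gave 5 higher and 1 lower.

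Control replicate 3 stood apart from the other libraries, and its values enter every control mean. Its correlation with the others across genes was 0.958 to 0.977, while TPPU replicates 2 and 3 correlated with each other at 0.991. The first principal component held 52.8% of the variance and put it at 31.4, with the others between -14 and 5. Its deviations from the gene means had a Spearman's rho of 0.61 with transcript GC content (across genes, which are not independent replicates), and those of TPPU replicate 1 had a rho of 0.24. Transcripts of the mitochondrial genome made up 0.371% of FPKM in control replicate 3 and 0.914% in TPPU replicate 1, against 1.46% to 1.85% in the other 4 libraries. Most of that share was mt-Co1, at 784 and 2418 FPKM in those libraries and 3803 to 4833 in the other 4. The genes mt-Nd4 and mt-Co2 were also lowest in those libraries, but mt-Co3 was not (3.67 and 3.01, against 2.16 to 4.75). The fold changes of TPPU against control had a rho of -0.29 with GC content and of -0.15 with transcript length.

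**Figure D1:**
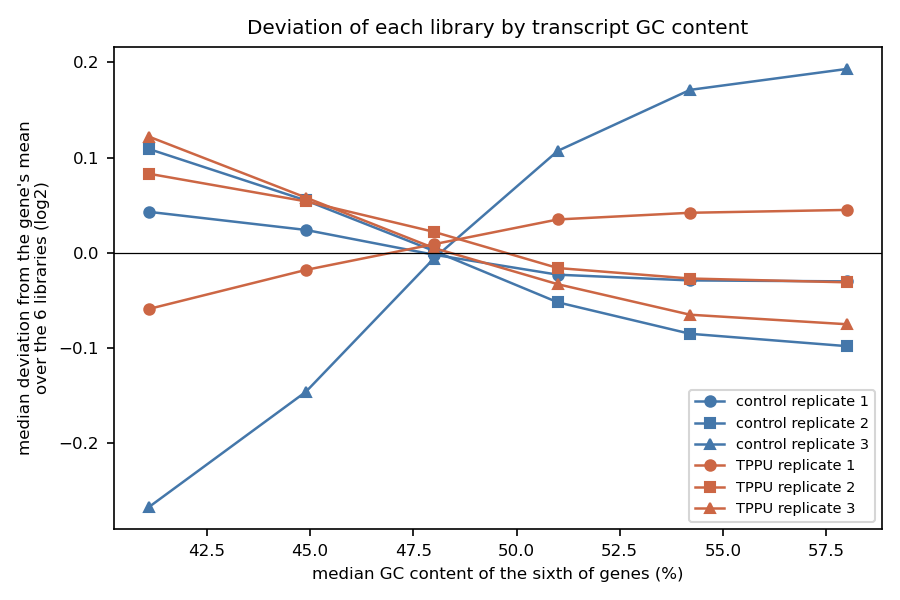
Median deviation of each library from the gene's mean over the 6 libraries (log2, vertical axis) for 6 groups of genes ordered by transcript GC content (percent, horizontal axis), with controls in blue and TPPU in orange. Control replicate 3 runs from -0.267 in the lowest group to 0.193 in the highest, and TPPU replicate 1 from -0.059 to 0.045.

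The M1 markers Nos2, Tnf, Il1b, Il6, Ptgs2, Il12b and Cd86 had values that overlapped between the groups. Nos2, which encodes inducible nitric oxide synthase, measured 118 ± 24.7 in control and 97.3 ± 7.02 with TPPU, a log2 change of -0.26 (SE 0.14, limma adjusted p = 0.667), or -0.09 (SE 0.08) without control replicate 3. Tnf measured 317 ± 138 and 178 ± 11, a change of -0.73 (SE 0.29, limma adjusted p = 0.591), and its 3 control values were 176, 322 and 452. Without control replicate 3 the change in Tnf was -0.42. Il1b measured 44.2 ± 12.8 and 46.3 ± 0.95, and Ptgs2, which encodes cyclooxygenase 2, 1479 ± 196 and 1413 ± 80.7. Il6 was at 8.45 in control replicate 3 and 11 in TPPU replicate 1, the libraries with the lowest mitochondrial share, and between 34.5 and 47.8 in the others. Its change of 0.09 (SE 0.65) turned to -0.63 without control replicate 3. Cd86 measured 1.62 ± 0.33 and 1.61 ± 0.38, and Il12b 1.09 ± 0.23 and 1 ± 0.46. For the M1 list of 22 genes camera gave an adjusted p of 0.414. Its median of -0.01 was 0, -0.06 and -0.08 without TPPU replicates 1, 2 and 3, and -0.02, 0.02 and -0.1 without control replicates 1, 2 and 3, with camera adjusted p from 0.144 to 0.73. No member passed over all genes or adjusted over the list alone. In 3 of the 22 all TPPU values lay below all control values, among them Socs3, a feedback inhibitor of cytokine signalling, at 71.5 ± 29.2 and 39.6 ± 3.72. The member with the smallest p was Il18, chosen after its values were seen, at 13.7 ± 1.68 and 21.2 ± 4.97 (log2 change 0.58, SE 0.18, limma adjusted p = 0.519).

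**Figure D2:**
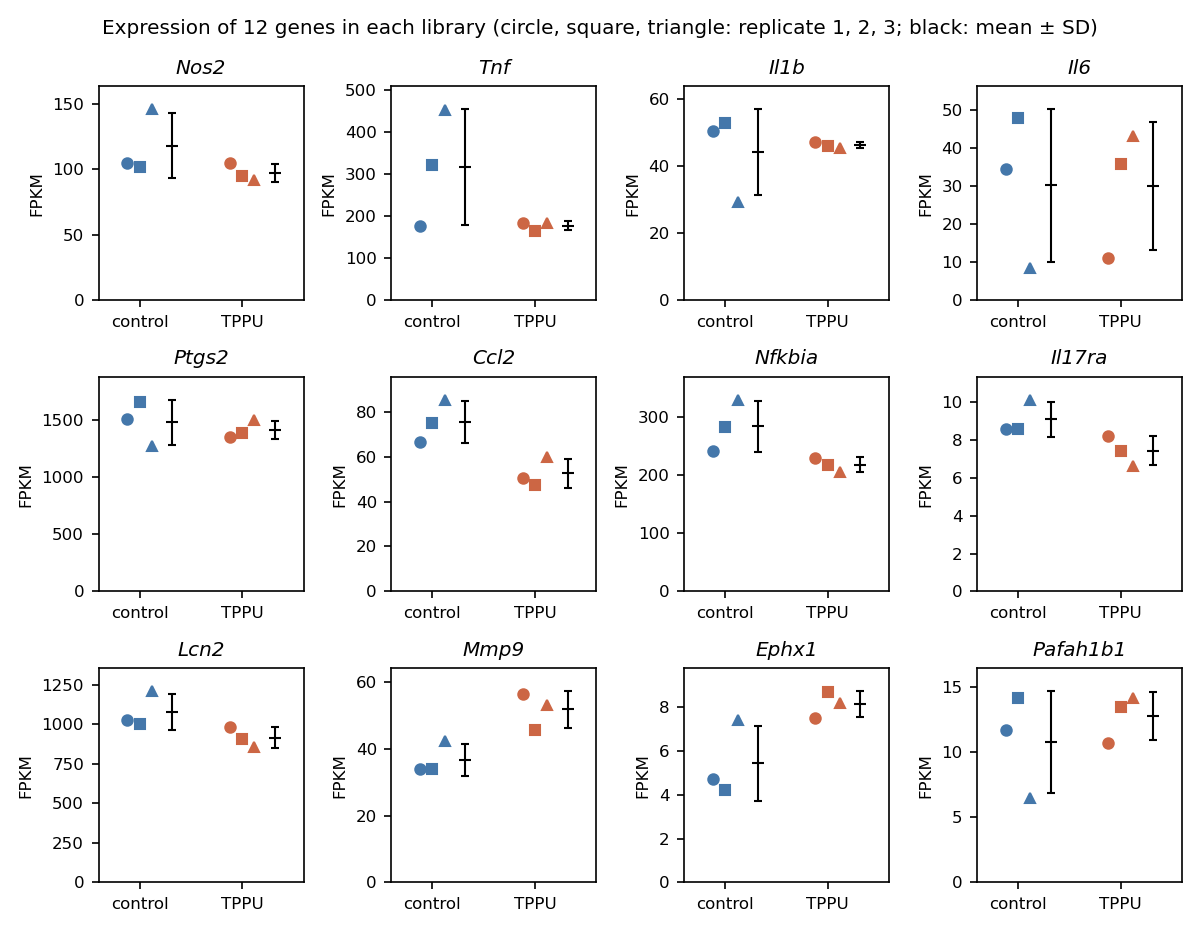
FPKM (vertical axis, from 0) of 12 genes in each library of the control group (blue) and the TPPU group (orange), with the mean ± SD of 3 libraries in black. Il6 is at 8.45 in control replicate 3 and 11 in TPPU replicate 1, while Ccl2 lies between 66.4 and 85.2 in control and between 47.5 and 59.9 with TPPU.

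Genes of the IL-17 pathway were lower as a group after TPPU. Of 45 members measured, 29 had a negative change and 16 a positive one, with a median of -0.08 (camera adjusted p = 8.02e-05). With an estimated correlation the call was lost (camera adjusted p = 0.181). The estimate for this list was -0.02, under the preset 0.01, so a higher correlation among its members does not account for the loss. The fewer degrees of freedom of that form of camera also weaken the test. No member passed over all genes, and adjusted over the list alone 9 were lower and 1 was higher. The chemokine gene Ccl2 measured 75.5 ± 9.43 in control and 52.6 ± 6.49 with TPPU (log2 change -0.51, SE 0.13, limma adjusted p = 0.397 over all genes), and Ccl7 6.97 ± 1.24 and 3.65 ± 0.77. Csf2, which encodes the growth factor GM-CSF, measured 28 ± 1.42 and 18.2 ± 3.57. Tnfaip3, which encodes the ubiquitin-editing inhibitor A20, measured 13.7 ± 0.14 and 9.22 ± 0.42. The matrix protease gene Mmp9 was the higher member, at 36.7 ± 4.8 and 51.8 ± 5.52 (log2 change 0.49, SE 0.12). The receptor gene Il17ra measured 9.08 ± 0.91 and 7.43 ± 0.78, Traf3ip2, which encodes the adaptor of that receptor, 6.38 ± 0.36 and 5.98 ± 0.75, Lcn2 1081 ± 114 and 917 ± 64.4, and Cxcl2 691 ± 62.9 and 626 ± 52.4. The median was -0.12 without control replicate 1, control replicate 3 or TPPU replicate 1. Il17a, the gene of the cytokine itself, was not analysed here.

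The list of NF-κB components and feedback regulators, 31 genes, was lower by a small margin, with a median of -0.04 and 18 negative changes (camera adjusted p = 0.03). The call was lost with an estimated correlation (adjusted p = 0.397 with an estimated correlation). It was also lost without control replicate 1 (camera adjusted p = 0.17), without TPPU replicate 1 (0.0911) and without TPPU replicate 3 (0.0707), and the median was -0.11 without control replicate 2 and -0.08 without TPPU replicate 1. Adjusted over the list alone, Tnfaip3 alone was lower. Nfkbia, which encodes the inhibitor IκBα, measured 284 ± 44 in control and 218 ± 12.2 with TPPU (log2 change -0.37, SE 0.12, limma adjusted p = 0.554). The subunit genes Nfkb1 and Rela measured 31 ± 3.74 and 28.8 ± 5.57 in control, and 29.3 ± 1.38 and 25.7 ± 3.39 with TPPU.

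The largest median shift of any list tested was that of the immediate-early genes (camera adjusted p = 1.01e-14 over 31 lists). With an estimated correlation, 0.26 for this list, and the fewer degrees of freedom of that test, the call was lost (camera adjusted p = 0.253). Adjusted over the list alone, 10 of 22 were lower and 0 higher, and 11 had all TPPU values below all control values. Klf6, a zinc-finger transcription factor on chromosome 13 (5861482 to 5870394, mm10), measured 59.3 ± 2.65 in control and 38.2 ± 1.62 with TPPU (log2 change -0.62, SE 0.09, limma adjusted p = 0.122). Dusp1 changed by -0.93 (SE 0.13, limma adjusted p = 0.128), Ier2 by -0.78 (SE 0.15) and Egr1, on chromosome 18 (34859823 to 34864984), by -1.05 (SE 0.21). The median was -0.27 without control replicate 3, where camera gave an adjusted p of 3.07e-11. Egr1 stood at 29.9 in that library against 19 and 19.9 in the other controls.

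Interferon-response genes, chemokines and p53 targets were also called lower by camera at the preset correlation. Of 41 interferon-response genes 21 had a negative change and 20 a positive one (median -0.02, camera adjusted p = 0.00834, and adjusted p = 0.357 with an estimated correlation). Adjusted over the list alone 2 were lower. Cmpk2 measured 11.7 ± 1.11 in control and 5.83 ± 0.51 with TPPU, and Rsad2, which encodes the antiviral enzyme viperin, 105 ± 17.5 and 69.5 ± 6.67. For 13 chemokine and receptor genes the median was -0.14 (camera adjusted p = 0.0104, and adjusted p = 0.289 with an estimated correlation), with 4 lower adjusted over the list alone. Cxcr4 measured 2.98 ± 0.43 and 1.6 ± 0.25. For 25 p53 targets the median was -0.08 (camera adjusted p = 0.007, and adjusted p = 0.253 with an estimated correlation). This was the list that fry also called (adjusted p = 0.0399). The estimated correlations of the interferon, chemokine and p53 lists were 0.02, -0.01 and -0.01, near the preset 0.01. Mdm2, which encodes the ubiquitin ligase of p53, measured 41.9 ± 3.46 and 31.9 ± 1.2, and Pmaip1, which encodes the cell death protein NOXA, 8.46 ± 0.58 and 5.71 ± 0.94. The interferon median was -0.11 without control replicate 3 and -0.03 without each of control replicates 1 and 2 and TPPU replicates 2 and 3, and the p53 median was -0.14 without TPPU replicate 1. The interferon call was lost without control replicate 2 (camera adjusted p = 0.0899) or TPPU replicate 1 (0.11), and the chemokine call without control replicate 2 (0.0652). With no filter on low values all 3 calls were lost (camera adjusted p = 0.0559 for interferon response, 0.452 for chemokines and 0.0652 for p53 targets).

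Genes of glycolysis and hypoxia, of lysosomes and autophagy, and of matrix proteases with their inhibitors were lower as groups too. The glycolysis list of 32 genes had a median of -0.06 (camera adjusted p = 0.00807, and adjusted p = 0.55 with an estimated correlation). Its member Pfkfb3, an activator of glycolysis, measured 75.2 ± 2.71 in control and 53.4 ± 2.18 with TPPU and was the 1 gene lower adjusted over the list alone. The glucose transporter gene Slc2a1 measured 204 ± 37.7 and 150 ± 7.05. For 38 lysosomal and autophagy genes the median was -0.05 (camera adjusted p = 0.00807, and adjusted p = 0.59 with an estimated correlation), and Gpnmb measured 42.8 ± 10.2 and 31 ± 0.3. For 17 protease and inhibitor genes the median was -0.08 (camera adjusted p = 0.0443, and adjusted p = 0.59 with an estimated correlation), with Plau at 56.2 ± 10.6 and 43.1 ± 1.65. Without control replicate 3, which stood apart, the glycolysis median was 0 (camera adjusted p = 0.0872), the lysosomal median 0.01 (0.229) and the protease median -0.09 (0.0813). The glycolysis median was -0.1, -0.11 and -0.09 without control replicates 1 and 2 and TPPU replicate 1, and the lysosomal median -0.12 and -0.1 without control replicates 1 and 2. The protease median was -0.12, -0.04 and -0.04 without TPPU replicates 1, 2 and 3, and that call was lost without control replicate 2 (camera adjusted p = 0.0578), TPPU replicate 2 (0.158) or TPPU replicate 3 (0.0695). With sample quality weights the lysosomal and protease calls were lost (camera adjusted p = 0.327 and 0.0507), and the protease call also at a mean of at least 5 FPKM (0.0998), with quantile normalization (0.0797) and without the trend (0.0547).

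Ribosomal protein genes were higher as a group after TPPU, with 43 of 47 changes positive (median 0.12, camera adjusted p = 7.34e-07, and adjusted p = 0.379 with an estimated correlation). With a trend on transcript length removed, a step added after the data were seen, the median was 0.04 (camera adjusted p = 0.00274). Adjusted over the list alone 2 were higher. Rpl14 measured 200 ± 8.93 in control and 258 ± 6.69 with TPPU (log2 change 0.37, SE 0.08, limma adjusted p = 0.372), and Rps25 217 ± 15.7 and 281 ± 26.6. Ribosomal protein genes have many processed pseudogenes, so their levels depend on how shared reads were counted. Of 33 nuclear genes of oxidative phosphorylation 31 had positive changes (camera adjusted p = 0.00085, and adjusted p = 0.379 with an estimated correlation), with Ndufb3 at 20.7 ± 3.83 and 27.6 ± 3.68 and Uqcrq at 21.3 ± 0.52 and 25.2 ± 2.47. The median of that list was 0.13, or 0.07 with the length trend removed (camera adjusted p = 0.033), and no member passed adjusted over the list alone.

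Genes of the cell cycle, lipid efflux and cholesterol synthesis were also higher as groups. For 36 mitotic genes the median was 0.15 (camera adjusted p = 0.00255, and adjusted p = 0.574 with an estimated correlation), with the kinase gene Plk1 at 3.62 ± 0.27 in control and 4.8 ± 0.39 with TPPU. For 36 genes of DNA replication it was 0.1 (camera adjusted p = 0.0225, and adjusted p = 0.379 with an estimated correlation), with Tk1, thymidine kinase, at 3.37 ± 0.23 and 4.68 ± 0.24. For 19 genes of lipid efflux and lipogenesis it was 0.15 (camera adjusted p = 0.007, and adjusted p = 0.397 with an estimated correlation). Lpl, lipoprotein lipase, measured 27.5 ± 1.69 and 38 ± 1.57 and was the 1 member higher adjusted over the list alone. For 25 genes of cholesterol synthesis the median was 0.1 (camera adjusted p = 0.0471, and adjusted p = 0.397 with an estimated correlation), with Acat2 at 8.44 ± 0.64 and 11.2 ± 1.72. The mitotic median was 0.06 without control replicate 3 (camera adjusted p = 0.507), and the DNA replication call was lost without that library (0.0806), control replicate 2 (0.0767, median 0.06) or TPPU replicate 1 (0.0816, median 0.06), with a median of 0.17 without TPPU replicate 3. The lipid call was lost without control replicate 2 (0.0767) or TPPU replicate 1 (0.0506). The cholesterol call was lost without control replicate 1 (0.138), control replicate 2 (0.179, median 0.06), TPPU replicate 1 (0.173) or TPPU replicate 3 (0.0534). With sample quality weights the mitotic and DNA replication calls were lost (camera adjusted p = 0.491 and 0.13). At a mean of at least 5 FPKM the DNA replication and cholesterol calls were lost (0.305 and 0.0781), and the cholesterol call also with quantile normalization (0.0561) and without the trend (0.0531).

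**Figure D3:**
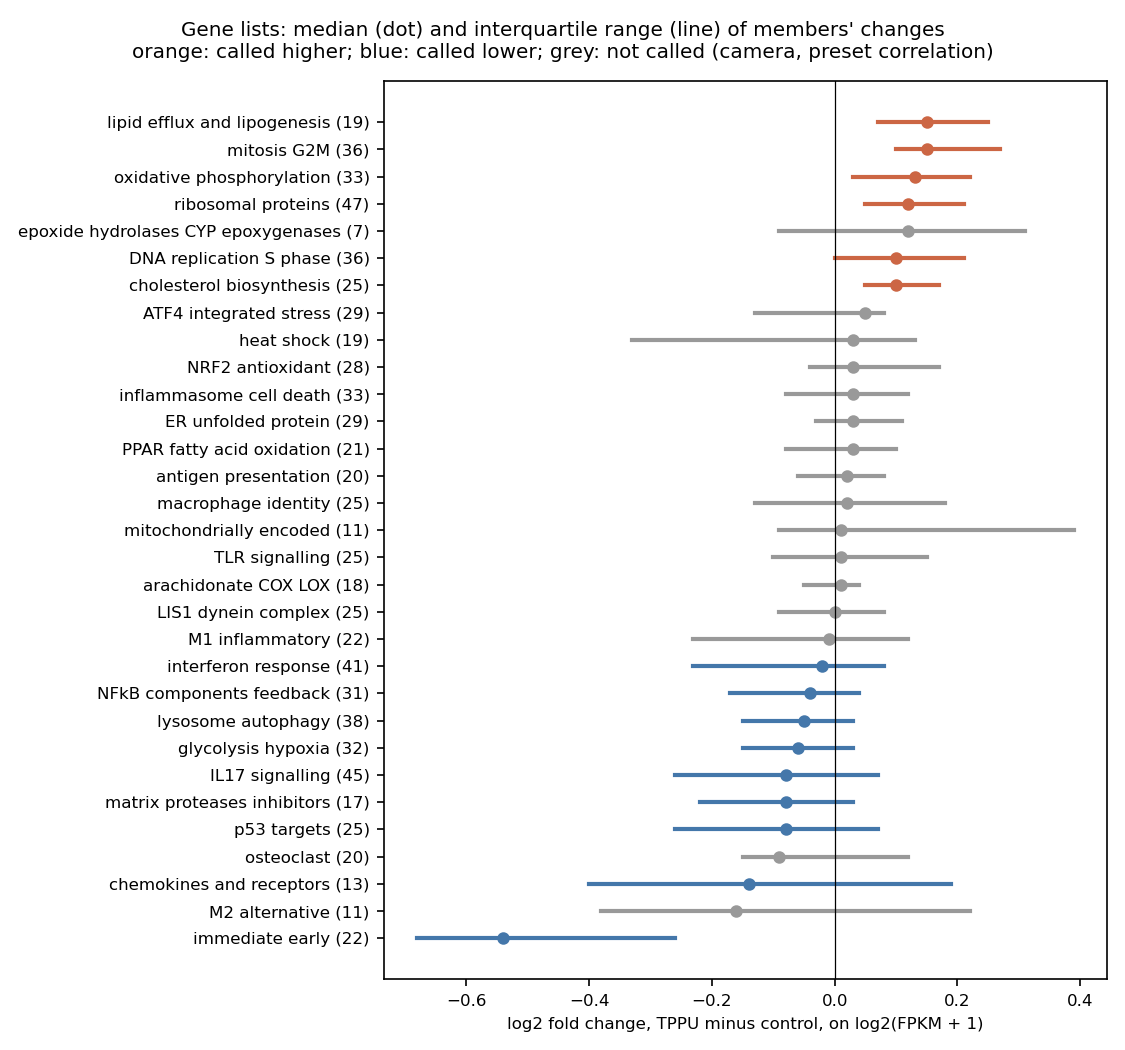
Log2 fold changes of TPPU against control (horizontal axis) for 31 gene lists (vertical axis, with the number of genes tested), as the median (dot) and interquartile range (line) over members. Lists called higher by camera are orange, lists called lower are blue and the others grey, and immediate-early genes have the lowest median, -0.54.

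The other 16 lists did not pass, with camera adjusted p from 0.0985 to 0.999. Genes of alternative macrophage activation had a median of -0.16 over 11 members (camera adjusted p = 0.0985). That list was called lower without control replicate 3 (camera adjusted p = 0.0254), without TPPU replicate 2 (0.0322) and at a mean of at least 5 FPKM (0.0169), while its median was -0.06 without TPPU replicate 1 and 0.01 without TPPU replicate 3. Adjusted over the list alone 2 of them were lower, Il1rn, which encodes the interleukin 1 receptor antagonist, at 459 ± 68 in control and 312 ± 20.7 with TPPU, and Myc at 7.66 ± 1.27 and 4.42 ± 1.01. Arg1, which encodes arginase 1, measured 1.4 ± 0.51 and 2.25 ± 1.18. Mrc1 and Il10 lay below the filter, with Il10 at 0.37 ± 0.18 and 0.39 ± 0.16. Osteoclast genes had a median of -0.09 over 20 members (camera adjusted p = 0.414), which was -0.05 and -0.02 without control replicates 1 and 3 and -0.01 without TPPU replicate 3, and macrophage identity genes 0.02 over 25 (0.807). Heat shock genes had a positive median, 0.03, with a negative mean, -0.16, and camera gave a downward direction (adjusted p = 0.545). They were called lower without control replicate 3 (median -0.07, camera adjusted p = 0.000621) and with sample quality weights (0.00144), which weighted control replicate 1 highest. Without control replicate 1 the heat shock median was 0.01 (camera adjusted p = 0.735). With an estimated correlation and all libraries camera gave an adjusted p of 0.917. The Toll-like receptor list had a median of 0.01 and a downward camera direction (adjusted p = 0.807), with medians from -0.04 to 0.02 with a library left out, and for macrophage identity these ran from -0.02 to 0.

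Transcripts of the enzyme that TPPU inhibits were scarce, though above the floor of 0.132 to 0.169 FPKM in every library. Ephx2, soluble epoxide hydrolase, on chromosome 14 (66084374 to 66124500), measured 0.86, 0.45 and 0.63 in the controls and 0.42, 2.56 and 1.54 in the TPPU libraries, below the filter (two-sided exact permutation p = 0.4, where 0.1 is the smallest that n = 3 against 3 allows). Ephx1, the microsomal epoxide hydrolase, measured 5.44 ± 1.72 in control and 8.14 ± 0.6 with TPPU (log2 change 0.54, SE 0.18, limma adjusted p = 0.562). The epoxygenase gene Cyp2j6 was below the filter. For 7 epoxide hydrolase and cytochrome P450 genes the median was 0.12 (camera adjusted p = 0.351), or 0.02 without TPPU replicate 2 and 0.07 without control replicate 2. Pafah1b1, which encodes LIS1, measured 10.8 ± 3.92 in control and 12.8 ± 1.87 with TPPU (log2 change 0.28, SE 0.24), and -0.02 without control replicate 3, so it was not lower in the libraries whose labels also carry an sh-LIS1 column name. The 25 tested genes of the LIS1 and dynein complex had a median of 0 (camera adjusted p = 0.545), from -0.06 to 0.02 with a library left out.

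Transcripts typical of hepatocytes differed between the TPPU libraries. The summed FPKM of 55 hepatocyte markers, listed after Apoh, Fabp1 and Ttr had been seen to vary, was 190, 170 and 178 in the controls, 185 in TPPU replicate 1, and 465 and 403 in TPPU replicates 2 and 3. Ephx2 and Arg1 belong to the genes that hepatocytes express at high levels, and both were highest in those 2 libraries. Markers of fibroblasts and chondrocytes summed to 10.4 ± 3.32 in control and 6.49 ± 1.27 with TPPU (two-sided exact permutation p = 0.2). With no filter on low values that list was called lower (median -0.04 over 21 genes, camera adjusted p = 0.0138), with 20 of the 21 averaging under 1 FPKM. The sums for lymphoid cells were 5.83 ± 1.23 and 6.11 ± 0.52, and for neutrophils and dendritic cells 10.8 ± 1.05 and 11.2 ± 1.38 (exact permutation p = 0.7 for each). For epithelial and endothelial cells they were 1.27 ± 0.35 and 1.46 ± 0.43 (exact permutation p = 0.5).

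**Figure D4:**
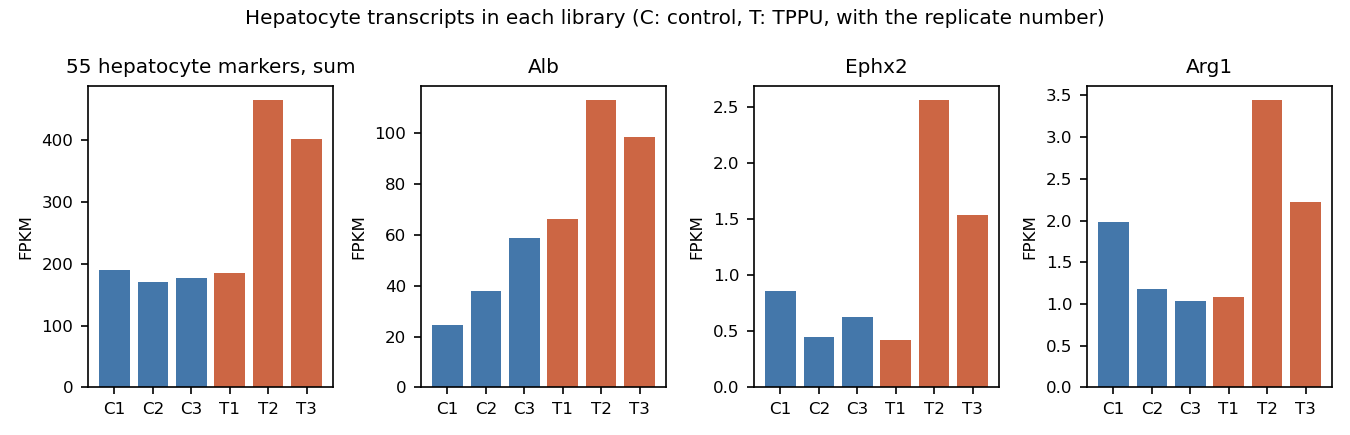
FPKM (vertical axes, from 0) of 55 hepatocyte markers summed and of Alb, Ephx2 and Arg1 in each control (C, blue) and TPPU (T, orange) library, with the replicate number. The marker sum is 465 and 403 in TPPU replicates 2 and 3 and at most 190 in the other 4 libraries.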

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

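Removal of the GC or length trend was added after the data were seen, and the other alternatives were fixed before. The counts of genes higher and lower, 0 and 0, were 89 and 80 with sample quality weights, 0 to 5 and 0 to 1 with a library left out in turn, and 0 and 0 in every other setting run. The 15 lists called became 0 with an estimated correlation, 1 with fry and 9 to 15 with a library left out, and were 13 with no filter (12 of them among the 15, and the fibroblast and chondrocyte markers), at a mean of at least 5 FPKM, with quantile normalization or without the trend, 12 with quality weights, and 15 in the other settings. Fry's mixed test, which ignores direction, called 6 lists. The smallest adjusted p was that of lipid efflux and lipogenesis (fry mixed adjusted p = 8e-05), then chemokines (0.00953) and immediate-early genes (0.0306). Ribosomal proteins, alternative macrophage activation, and PPAR with fatty acid oxidation followed at 0.0334 each. The last 2 were not called by camera. The mixed test does not ask whether a list moved one way. The IL-17 list lost its call with an estimated correlation (adjusted p = 0.181) and with fry (0.115), and kept it with each library left out. The NF-κB list lost it with an estimated correlation (0.397) and with fry (0.3), and ranged from 0.0123 to 0.17 with a library left out. The M1 list passed under no setting run. With the GC trend removed the NF-κB median was -0.07 and the interferon median -0.04, and with the length trend removed the glycolysis median was -0.09, the interferon median -0.03 and the p53 median -0.12, all with the call kept. The cause was not tested.

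Of 87 named genes under 1550 alternatives, 1514 kept direction and side of the threshold, 21 passed it in the same direction and 15 turned direction, none of these past the threshold. The log2 change of Il1b turned to -0.11 and that of Il6 to -0.17 with quality weights, and Il6 to -0.02 with the GC trend removed. With a library left out, Il6 ranged from -0.63 to 0.67, Il1b from -0.15 to 0.26, Pafah1b1 from -0.02 to 0.49, Cd86 from -0.11 to 0.11, Ptgs2 from -0.16 to 0.03, Nfkb1 from -0.16 to 0.01, Il12b from -0.26 to 0.03 and Traf3ip2 from -0.15 to 0. With each group's mean subtracted from every gene, the deviations of same-numbered libraries correlated at -0.3, 0.15 and -0.4. No pairing by replicate number was seen, though so few libraries cannot rule it out. The number as a replicate block gave 0 genes higher, 0 lower and 15 lists. Depth limits genes near 0.169 FPKM, such as Mrc1 and Cyp2j6.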

Other observations

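Among the tests reported here, those of the GC trend and of depth in control replicate 3, of other tissues and of a TPPU response for the hepatocyte markers, of GC for the immediate-early and ribosomal lists, the separate readings of those 2 lists, and the splits for gene counts were chosen only after the result was seen, as were removal of the GC or length trend, the reduced IL-17 list and the bootstrap intervals of the shares of a median kept.

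Replication histone transcripts, which mostly lack a poly(A) tail, summed to 29.8 ± 2.89 FPKM in control and 15.6 ± 1.25 with TPPU over 12 genes, with all 3 TPPU libraries below all 3 controls (two-sided exact permutation p = 0.1, the smallest that n = 3 against 3 allows). Most of that sum was H1f2, a linker histone gene chosen after its values were seen, at 24.9 ± 3.32 and 11.8 ± 0.58 (limma log2 change -1.02, SE 0.12, adjusted p = 0.116). A further pair of genes parted TPPU replicates 2 and 3 from the rest and were also chosen after their values were seen. Cfd, which encodes complement factor D, measured 3.13, 3.47 and 3.58 in the controls and 3.28, 0.048 and 0 in TPPU replicates 1, 2 and 3. Rps27a measured 187, 204 and 157 in the controls and 151, 427 and 441 in the TPPU libraries. Leaving out TPPU replicate 1 made Cfd the 1 gene lower (limma log2 change -2.1, adjusted p = 0.0143), and the 5 higher genes were Fabp1, Ahsg, Serpina1b, Apoh and Rps27a (adjusted p up to 0.0365).

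With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. All 10 gave as many changed genes, since each gave 0. At an unadjusted p under 0.05, 3 splits gave at least the 768 genes of the real one, and the highest other gave 1046. That split set control replicates 1 and 3 with TPPU replicate 1 against the rest, and so put the 2 libraries with a positive GC trend on the same side. The real split called 15 lists and was the 1 with as many, the highest other calling 11. For the M1 list 2 splits gave an adjusted p as small as 0.414, the smallest other being 0.371. For the NF-κB list 2 did, with 0.0278 as the smallest other against 0.03. For the IL-17 list it was 1, with 0.0245 as the smallest other, and for the immediate-early list 1, with 9.17e-10.

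Control replicate 3 stood apart from all other libraries. Depth is argued against, since the estimate of 19.1 M fragments lies within the range of the other 5 libraries. A curve on GC content removed 0.344 of this library's squared deviation from the other controls, so a GC-dependent step in library preparation or sequencing may be part of the cause. The curve did not remove all of the difference. The SD of this library's deviations was 1.4 times that of the more variable of the other controls before removal and 1.35 times after. The bootstrap interval over genes was 1.31 to 1.38, against a bound of 1.3 chosen after the result, which it passes narrowly. The curve also narrowed the deviations of control replicate 2 (SD 0.29 to 0.24), so the ratio does not measure how much GC content explains. What remains is open, and no biological explanation was tested, as the labels give this library no property of its own.

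Hepatocyte transcripts were higher in TPPU replicates 2 and 3, where 52 of 55 markers exceeded all other 4 libraries. Chance gives 6.67% for a pair of libraries fixed in advance and independent genes. Here the list was written after Apoh, Fabp1 and Ttr had been seen to vary, and the pair came from the data. The count thus describes the pattern and does not test it. Alb, the most abundant liver transcript, measured 113 and 98.4 against 24.5 to 59 in the controls and 66.4 in TPPU replicate 1. The first test of liver RNA, fixed in advance as the summed FPKM of 40 further markers, went against it by its own bound: the lower of the 2 libraries was 0.978 times the highest of the others, where under 1.2 was to exclude it. That bound was wrong for this list, because Urah alone made up 68.7% to 88.3% of the sum at 96.4 to 127 FPKM in every library, and counted afterwards gene by gene 28 of the 40 exceeded the other 4. A further list of 44 markers, with a bound of 33 percent of genes fixed before their values were seen but after that failure, gave 36 (81.8%), and 33 of 41 without the Mup family, so a trace of liver RNA or reads is a candidate source, though 32 of the first 55 markers, 5 of the 40 and 5 of the 44 also averaged at least 1 FPKM in control. Traces of many tissues alike cannot be told apart. Of 54 markers of 5 other tissues 5 (9.26%) exceeded the other 4 libraries, but most were near the floor. Of the 14 that averaged at least 0.169 FPKM 2 exceeded (14.3%, exact interval 1.78 to 42.8 over genes, which it takes as independent though they share the same libraries). The median ratio of the sums of these 5 lists was 0.953. Each sum rests on a gene of its own, which made up 75.2% to 96.9% of it. A response to TPPU cannot be told apart either, since TPPU replicate 1, at 0.974 of the highest control, is 1 library. In it 10 of the 55 markers, Alb among them, lay above all controls and 13 below (25% each by chance). Fabp1, which is not in the list and was chosen after its values were seen, lay above (2.48 against 0.32 to 0.51).

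Immediate-early genes were lower and ribosomal protein genes higher with TPPU by camera with a preset correlation. These calls were lost with an estimated correlation (camera adjusted p = 0.253 and 0.379) and with fry (adjusted p = 0.0986 for each). The GC trend is argued against for both, as its removal kept 0.965 of the immediate-early median and 1.2 of the ribosomal one. Transcript length is argued against for the immediate-early genes, which kept 1.02, but not for the ribosomal genes, whose median kept 0.367 (0.12 to 0.04, bootstrap interval of the share over genes 0.0477 to 0.731) with the call held (camera adjusted p = 0.00274), so a length trend may be a large part of that shift, and as these transcripts are short as a class the correction could also remove a true shift. Control replicate 3 alone is argued against for the ribosomal genes, which kept 0.989 without it, but the immediate-early median kept 0.503 with its call held, between the bounds of 0.5 and 0.75, so how much of it comes from that library cannot be told apart. A weaker early response to LPS with TPPU and a difference in handling at harvest both stay open as hypotheses and were not tested.

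That the IL-17 list was lower through genes it shares with the immediate-early and NF-κB lists was tested by removing its 9 shared members. The other 36 kept a median of -0.06 (camera adjusted p = 0.00807, and 0.253 with an estimated correlation), 0.752 of the original. The bound of 0.75 was fixed before the reduced list was tested, though after the result of the full list was seen. The bootstrap interval of that share over genes ran from -0.599 to 1, so whether the shared genes make up the shift cannot be told apart.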
